A study of Mus musculus with 105 samples.

How the data were processed

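Poly(A) RNA was sequenced from mouse tumour lines, cultured melanocytes and healthy tissues, 105 libraries in all. The main comparisons use 45 cultured libraries of B16, B16OVA, MCA101OVA and MC38, each line with WT, Ctrl and Setdb1 KO groups of 3 to 6 libraries. The other libraries are 5 melanocyte libraries, 48 libraries of 12 healthy tissues (4 each) and 7 tumour WT libraries of run B176. These 7 were left out of every fit because that run holds no replicated group, and enter the Setdb1 levels and the search for tumour-restricted genes alone. The labels do not say whether replicates are separate cultures; if they are not, the p-values measure only the spread between these samples.

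The authors name Trim Galore, FastQC, STAR and HTSeq with the mm10 genome; versions, annotation and the strand setting are not given in the sources used here. The deposited raw table holds counts per Ensembl gene. A 2nd deposited table holds each library as a fraction: the authors divided each raw count by 1 whole number per library, which is 1.05 to 1.26 times the library's gene count total (checked on every value, largest relative deviation 5.773e-15); it was not used here. Of 53379 gene IDs, 53274 were matched to symbols through GENCODE vM21. Whether reads that map to several places were counted is not given either. Junctions with transposable elements cannot be read from gene counts and were not analysed here.

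Library totals, in units of 1e6 counts, were 17.2 to 50.4 in the 45-library fit, 19.9 to 30.6 in melanocytes and 53.6 to 254 in tissues. At these depths 1 CPM is at least 17.2 counts. Intervals of ratios are exact binomial at 95% and, like the floor of 3 counts over a group used for genes at 0, cover counting error alone. CPM values are plain counts per 1e6 counts of the library total.

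Counts were analysed in R 4.3.3 with edgeR 4.0.16 (TMM, filterByExpr by group, quasi-likelihood fit and test, Benjamini-Hochberg adjustment, called at an adjusted p under 0.05). The fit held a term for each group and one for the run code in the library names; 16809 genes were tested with 31 residual degrees of freedom and a common biological coefficient of variation of 0.401. KO was set against Ctrl and Ctrl against WT in each line, and the KO effect of each line against that of B16OVA. WT contrasts used libraries that share runs: 3 B16OVA WT against 5 melanocyte libraries, 3 against 3 MC38 and 3 against 3 MCA101OVA. In tissues, a gene counted as highest in 1 tissue at an adjusted p under 0.05, a log2 fold of at least 2 against the mean of the others and the highest mean CPM. Of 28 gene lists, 26 were tested in the KO comparisons with camera (limma 3.58.1, preset correlation 0.01; the others had too few tested genes), and with an estimated correlation and fry as alternatives.

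The comparisons, lists, the naming rule and most alternatives were fixed before the data were examined. The rule names called genes with a mean of at least 1 CPM, 1 direction in every run and a symbol that is no predicted model: the 8 highest and 6 lowest by log2 fold per KO or WT contrast, 5 and 5 per interaction, up to 3 called members per list and 2 genes per tissue, with the tumour-restricted genes by mean CPM. The text names part of them.

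Alternatives were RLE size factors, no filter or a stricter one, DESeq2 1.42.0, no run term, the library-number set as a replicate block, a 2-fold minimum, the 2 groups alone in the fit, WT in place of Ctrl and each library left out. Chosen after seeing the data were the fits without 7 libraries whose log CPM falls with transcript length (slope under -0.15), with that slope as a covariate, with Ctrl and WT together, with a block by line, a background matched on KO level, and the tests of interferon-stimulated genes inside library sets. Whether library numbers pair the samples was decided before calls were compared, from the correlation of deviations from group means: in B16 and MCA101OVA 9 of 9 pairs of 1 set were over 0.1 (lowest 0.31 and 0.29), and in B16OVA 12 of 12 KO and Ctrl pairs (lowest 0.43) but 29 of 36 with WT pairs included (lowest -0.55). In MC38, 9 of 9 pairs by place were over 0.1 (lowest 0.11), a hint from the data alone. The main fit, with its run term, does not use these pairs. They enter only the alternatives with a replicate block. The fits were tested on simulated data with genes changed by set folds, which gave 7, 6, 5 and 8 false calls in B16, B16OVA, MCA101OVA and MC38. These were 4.67%, 3.51%, 4.07% and 5.63% of the calls. All 169 pairs of libraries within groups were checked for duplicates, and 0 were identical.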

Results

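Setdb1 encodes a histone H3 lysine 9 methyltransferase that silences repeats and the genes near them. Its loss was read at gene level in 4 mouse tumour lines (B16, B16OVA, MCA101OVA and MC38), each with WT, control (Ctrl) and Setdb1 knockout (KO) libraries. The Setdb1 transcript was lower in KO than in Ctrl by group mean in all 4 lines. Mean levels went from 62.2 ± 2.77 to 17.1 ± 4.78 CPM (counts per 1e6 library counts, mean ± SD) in B16, 70.4 ± 27.7 to 33.5 ± 13.2 in B16OVA, 68.0 ± 25.5 to 27.9 ± 8.22 in MCA101OVA and 101 ± 39.8 to 73.2 ± 12.7 in MC38. The WT libraries of these lines held 66.4 ± 13.3, 70.98 ± 19.4, 79.5 ± 12.3 and 119 ± 10.6 CPM of Setdb1. Setdb1 fell by 1.85 (SE 0.29) on the log2 scale in B16 (edgeR, adjusted p = 9.8e-05), by 1.18 (SE 0.20) in B16OVA (adjusted p = 2.17e-04) and by 1.40 (SE 0.29) in MCA101OVA (adjusted p = 0.00749). In MC38 Setdb1 fell by 0.52 (SE 0.28) and was not called (edgeR, adjusted p = 1 over all tested genes). Much of the spread between MC38 Ctrl libraries came from Ctrl replicate 1, with 54.9 CPM and a low length slope (-0.385). Ctrl replicates 2 and 3 held 122.7 and 124.9 CPM. They and every MC38 WT library (lowest 107.8) lay above every MC38 KO library (highest 85.3). The MC38 log2 fold stayed between -0.775 and -0.357 with any library left out. The counts do not read the protein. With any library left out the MCA101OVA log2 fold of Setdb1 stayed between -1.45 and -1.29, but its call was lost without Ctrl replicate 1 (adjusted p = 0.142), KO replicate 1 (0.0524), Ctrl replicate 2 (0.0620) or KO replicate 2 (0.0891), and without the low-count filter (0.0943) or the sequencing-run term (0.0644).

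**Figure D1:**
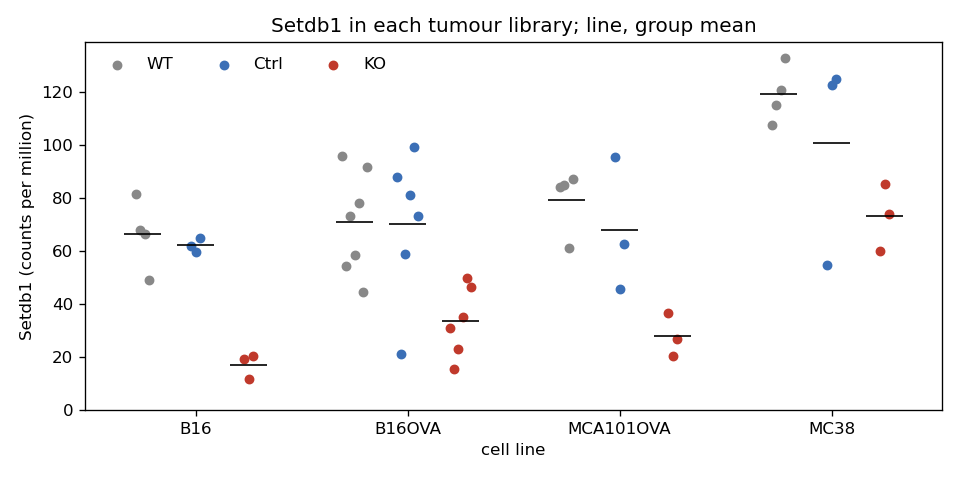
Setdb1 in CPM (vertical axis) in each WT, Ctrl and KO library of the 4 tumour lines (horizontal axis); each point is a library and each line a group mean. KO libraries lie below every Ctrl library in B16 and MCA101OVA, and the KO and Ctrl ranges overlap in B16OVA and MC38.

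Loss of Setdb1 raised genes far more often than it lowered them. KO against Ctrl called 116 genes in B16 (111 up, 5 down), 177 in B16OVA (167 up, 10 down), 58 in MCA101OVA (57 up, 1 down) and 78 in MC38 (78 up, 0 down), of 16809 tested. These calls rest on the 45-library fit, which estimates the spread of a gene over all lines. For B16, MCA101OVA and MC38 the 10 splits of KO and Ctrl libraries are too few to weigh the counts against chance. Between Ctrl and WT libraries, which both keep Setdb1, edgeR called 0 genes in each line (1, 37, 5 and 40 with no filter, and 11 in B16OVA without 7 libraries of low length slope), with between 104 (B16) and 630 (B16OVA) genes per line at an unadjusted p under 0.05, and DESeq2 called 0, 0, 1 and 0. At these group sizes, 66%, 90%, 56% and 60% of genes changed 4-fold in simulated data were recovered in B16, B16OVA, MCA101OVA and MC38. Of those changed 2-fold, 24%, 42%, 4% and 16% were recovered, so smaller changes were mostly not detectable. The changed genes were taken above a minimum mean count, and libraries were simulated without run or library-set effects. Recovery of genes near 0 counts was not tested. With each line's library sets as a replicate block, B16OVA gave 275 genes and MC38 134. With the 2 groups of a line alone in the fit, B16 gave 22, MCA101OVA 1, MC38 2 and B16OVA, rounded, 1.1e2. The MC38 count was 33 without Ctrl replicate 2, 27 without Ctrl replicate 3 and 27 without KO replicate 1; the MCA101OVA count was 34 without Ctrl replicate 1, and the B16 count 74 without Ctrl replicate 1.

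In the B16 melanomas, some genes rose from near 0 in KO. The neuronal gene Sez6l rose from 0.0142 ± 0.0246 to 69.3 ± 16.2 CPM in B16 and from 0.00454 ± 0.0111 to 22.3 ± 10.5 in B16OVA. Against 2 and 1 Ctrl counts of Sez6l, the ratios are 4066 (95% counting interval 1125 to 33576) and 3585 (643 to 141620). In B16, Cyp3a41a (1149-fold against 2 Ctrl counts, 317.7 to 9493) and the retinal channel gene Cnga3 (258-fold against 3 Ctrl counts, 87.8 to 1252) rose from near 0, as did Bglap3 (log2 fold 8.47), Lhx9 (8.06), Efcab6 (7.83), Gabrr1 (7.41) and Padi3 (7.26). B16OVA showed Bglap3 (log2 fold 8.42), Cyp3a41a (8.21), Padi3 (6.95), Cnga3 (6.68), Zfp985 (6.25) and Gabrr1 (6.23), with Zfp981 426-fold against 1 Ctrl count (76.2 to 16871). The highest edgeR adjusted p of these 16 calls was 6.48e-07 (Gabrr1 in B16). B16 and B16OVA shared 100 of their 111 and 167 raised genes, where independent lists would share 1.10 (Fisher's exact test, 1-sided, p = 7.0e-203, genes not being independent replicates). Both are B16 melanomas fitted together, so independent lists were not to be expected. Among the few lowered genes, Smpdl3b fell by 1.52 on the log2 scale in B16OVA (SE 0.24, adjusted p = 8.87e-05). Which member of the near-identical Zfp, Cyp3a and Bglap families the reads came from is uncertain at gene level.

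In MCA101OVA, the P450 gene Cyp2b13 rose from 0 Ctrl counts to 4.09 ± 2.38 CPM, at least 104-fold over a floor of 3 counts in the Ctrl group (adjusted p = 6.61e-05). Vmn2r96 rose from 0 Ctrl counts to 2.17 ± 2.00 CPM, at least 42.2-fold (adjusted p = 0.00642), but its call was lost by DESeq2 (0.869) and without Ctrl replicate 1 (0.0883). The muscle gene Ky (418-fold against 3 Ctrl counts, interval 143 to 2027), Dpep1 (229-fold against 3, 78.1 to 1111), Tdrd9 (147-fold against 2, 40.5 to 1220), Klk1b24 (150-fold against 1, 26.6 to 5945) and the testis tubulin Tuba3a (154-fold against 1, 27.5 to 6125) rose too, with adjusted p from 1.33e-06 (Ky) to 0.00333 (Klk1b24). Ratios against so few counts depend on single libraries, and the log2 fold of Ky lay between 7.72 and 12.3 with any library left out. Bglap3 reached 78.0 ± 29.99 CPM from 0.186 ± 0.144 (log2 fold 8.66, SE 0.72, adjusted p = 5.78e-10). Of the 10 ways to divide the 6 libraries of MCA101OVA, 3 others called more genes than the real one. The 6 that leave 2 library sets whole on opposite sides called 0, 0, 12, 67, 292 and 3766. The other 3 divisions that part the 2 libraries of every set, as the real one does, called 0.

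In MC38, Pnma5 rose from 0.152 ± 0.0284 to 6.37 ± 1.38 CPM (log2 fold 5.27, SE 0.80, adjusted p = 1.87e-04), Bglap3 from 0.916 ± 0.211 to 20.5 ± 8.59 (4.40, SE 0.58, adjusted p = 3.78e-05) and Zfp518b from 0.149 ± 0.0960 to 3.34 ± 1.53 (4.36, SE 0.58, adjusted p = 3.78e-05). The surface antigen gene Cd34 rose from 2.41 ± 1.48 to 33.6 ± 26.8 CPM (log2 fold 3.71, adjusted p = 4.85e-04). Ky, Ndst4, Vldlr and Bcl6b were also called higher in MC38 (adjusted p = 0.00241, 0.0112, 0.0158 and 0.00487), and these 4 calls depend on which libraries are kept, though with any library left out the log2 folds stayed at 3.90 to 4.62, 3.18 to 4.71, 2.98 to 4.24 and 3.46 to 3.79. Without Ctrl replicate 2 their adjusted p were 0.0549, 0.121, 0.133 and 0.0806, and without Ctrl replicate 3 0.0621, 0.185, 0.226 and 0.0738. Without KO replicate 1 Ndst4 and Vldlr stood at 0.324 and 0.287, and Vldlr was also lost without the run term (0.0817).

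A small group of genes was called up in KO of all 4 lines. Zfp981, Bglap3, Tdrd9, Gm16897, Zfp978, Pla2g5, Gm8493 and Plb1 make 8 genes, where independent lists would share 1.74e-05. The lists are not independent, since B16 and B16OVA shared 100 raised genes and all 4 lists come from 1 fit. The value of 1.74e-05 therefore does not measure chance. A further 11 of the 276 raised genes were called in 3 lines. Those 11 include the germline genes Tex19.1 and Dppa4, the stress ligand gene Ulbp1 and the purinergic receptor gene P2rx7. Pla2g5 rose from 5.93 to 54.8 CPM in B16 (log2 fold 3.25), from 2.80 to 37.3 in B16OVA (3.65), from 0.0718 to 2.07 in MCA101OVA (4.68) and from 0.311 to 1.95 in MC38 (2.57). Tdrd9, of the piRNA pathway, reached 8.54, 4.26, 4.08 and 1.76 CPM in KO from 0.207, 0.203, 0.0279 and 0.0828 in Ctrl. P2rx7 reached 736 CPM in B16 KO and 797 in B16OVA KO, from 32.5 and 34.1. Setdb1 was the sole gene called down in 3 lines, and 0 genes were called down in all 4. Bglap3, Tdrd9, Pla2g5 and Gm8493 kept their calls in all 4 lines with any library left out. Zfp981, Zfp978 and Plb1 lost theirs in MCA101OVA without Ctrl replicate 1 (adjusted p = 0.339, 0.281 and 0.109), and Zfp981, Gm16897 and Plb1 in MC38 without KO replicate 1 (0.287, 0.344 and 0.439). Other single libraries brought these 4 genes to adjusted p between 0.0538 and 0.304, and 5 genes remained in all 4 lines without MC38 Ctrl replicate 2, Ctrl replicate 3 or KO replicate 1. Gm16897 overlaps Cd34 on the opposite strand, and the strand setting of the counts is not given. Reads of 1 counted for the other can therefore not be ruled out.

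**Figure D2:**
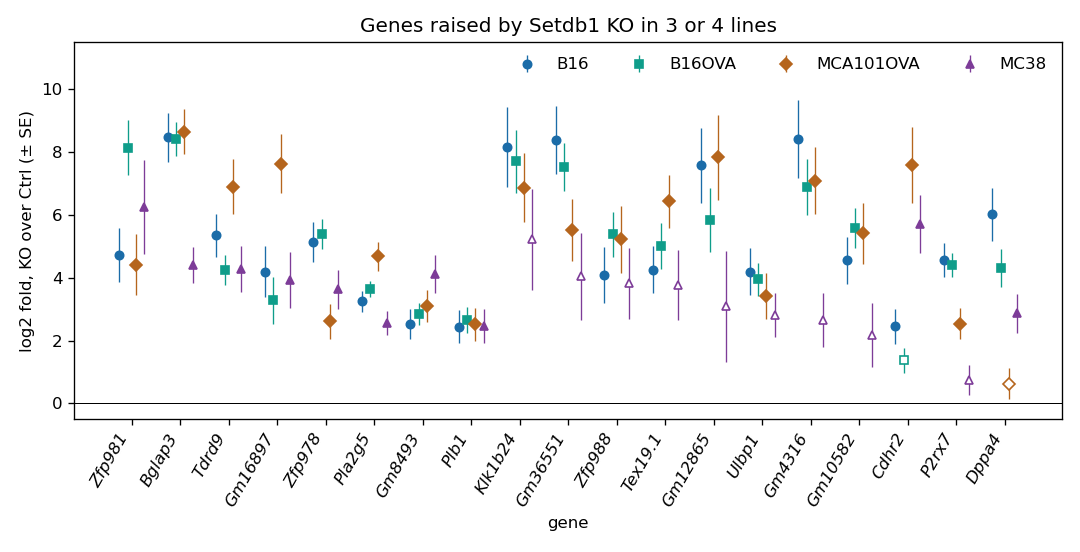
Log2 fold of KO over Ctrl with its SE (vertical axis) for the 19 genes called up in 3 or 4 lines (horizontal axis), by line; filled marks are called at an adjusted p under 0.05 and open marks are not. Bglap3 lies between 4.40 and 8.66 in the 4 lines, and most open marks belong to MC38.

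Among gene lists fixed beforehand, the germline list rose in all 4 lines (camera adjusted p = 1.35e-08 in B16, 8.84e-04 in B16OVA, 1.35e-08 in MCA101OVA and 1.35e-08 in MC38). With an estimated correlation its adjusted p was 0.00679 in B16, MCA101OVA and MC38 and 0.24 in B16OVA. Of 24 tested germline genes, 5, 3, 4 and 2 were called up in B16, B16OVA, MCA101OVA and MC38, and 6, 4, 6 and 4 when adjusted over the list alone. They include Tdrd9 in all 4 lines, Tex19.1 in B16, B16OVA and MCA101OVA, Dppa4 in B16, B16OVA and MC38, Rhox5 in B16 (14.6 against 0.976 CPM) and Rnf17 in MCA101OVA (2.01 against 0.0254 CPM). The Dppa4 call in MC38 was lost without Ctrl replicate 2 (adjusted p = 0.208), Ctrl replicate 3 (0.185) or KO replicate 1 (0.184). Dppa4 had an adjusted p of 0.887 in MCA101OVA, whose Ctrl libraries already held 3.31 CPM.

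The clustered protocadherins rose as a list in MCA101OVA (adjusted p = 1.75e-08; 0.299 with an estimated correlation) and MC38 (9.06e-11; 0.207 with an estimated correlation). Of 30 tested protocadherins, 3 were called up in MCA101OVA and 1 in MC38, or 7 and 4 when adjusted over the list alone. Pcdhgb2 rose from 0.549 to 7.27 CPM in MCA101OVA and from 0.425 to 2.90 in MC38. In the melanomas the list was not called (adjusted p = 0.0943 in B16 and 0.774 in B16OVA); 2 of the 30 were called up and 1 down in B16 (3 and 6 over the list alone), and 3 up and 1 down in B16OVA (4 and 6). Among these, Pcdhga12 and Pcdhgc5 rose (log2 fold 5.85 and 6.22 in B16, 4.26 and 4.65 in B16OVA), while Pcdhb11 fell by 2.90 in B16 and Pcdhb5 fell by 1.81 in B16OVA. Zinc finger genes with Zfp symbols rose as a list in B16OVA (adjusted p = 5.22e-08; 0.763 with an estimated correlation), MCA101OVA (1.56e-12; 0.426) and MC38 (0.00177; 0.965), with 10, 3 and 4 of 360 called up over all genes and 12, 7 and 4 when adjusted over the list alone; in B16, 7 were called up and 0 down (8 up over the list alone). The MC38 call of this list was lost without Ctrl replicate 1 (0.851) or KO replicate 2 (0.0600). The mean of the whole list in B16 was -0.01 and its median -0.16 (adjusted p = 0.258).

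Interferon-stimulated genes, a readout of sensed nucleic acids, were not called as a list on Setdb1 loss in the fit with a run term. Of 40 tested interferon-stimulated genes, edgeR called 0 in each line, also when adjusted over the list alone, and the camera adjusted p was 0.294 in B16, 0.51 in B16OVA, 0.742 in MCA101OVA and 0.0744 in MC38. The median log2 fold of the list was -0.42, 0.31, -0.13 and -0.42 in the same order. With each line's library sets as a replicate block, the list was called down in MC38 (camera adjusted p = 0.00307; 0.936 with an estimated correlation), and of its members Oas1g was called up in B16 (log2 fold 2.19, adjusted p = 0.00774) and B16OVA (1.87, 9.11e-04) and Oas1a in B16OVA (1.35, 0.0328). The list mean was lower in KO than in Ctrl and WT in 3 of 3 sets of B16 and 3 of 3 places of MC38, 2 of 4 sets of B16OVA and 2 of 3 of MCA101OVA; exchanging KO and Ctrl labels inside sets gave exact p = 0.25 in B16 and MC38, the smallest that 8 arrangements allow, 0.338 in B16OVA and 1 in MCA101OVA. MHC class I genes were not called as a list in any line (camera adjusted p from 0.572 to 0.932), though H2-Q4 in MC38 (2.51 against 0.410 CPM) and Tap2 in B16OVA (11.55 against 4.197 CPM) passed when adjusted over the list alone. Aim2, a DNA sensor, rose in MC38 from 0.221 ± 0.0967 to 1.76 ± 1.55 CPM (log2 fold 2.92, edgeR adjusted p = 0.00580), with a wide spread between KO libraries. The NK and checkpoint ligand list was called up in MC38 alone (camera adjusted p = 0.00477, and 0.24 with an estimated correlation). Its member H60b was called there (log2 fold 6.07, edgeR adjusted p = 0.00243), from 0 to 0.273 ± 0.187 CPM, which is near the count floor. Ulbp1 was called in the other 3 lines and had an adjusted p of 0.0607 in MC38. The list call was lost without MC38 Ctrl replicate 3 (0.0847) or KO replicate 1 (0.0508), and the Ulbp1 call in MCA101OVA without Ctrl replicate 1 (0.315), KO replicate 1 (0.1503) or Ctrl replicate 2 (0.205).

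**Figure D3:**
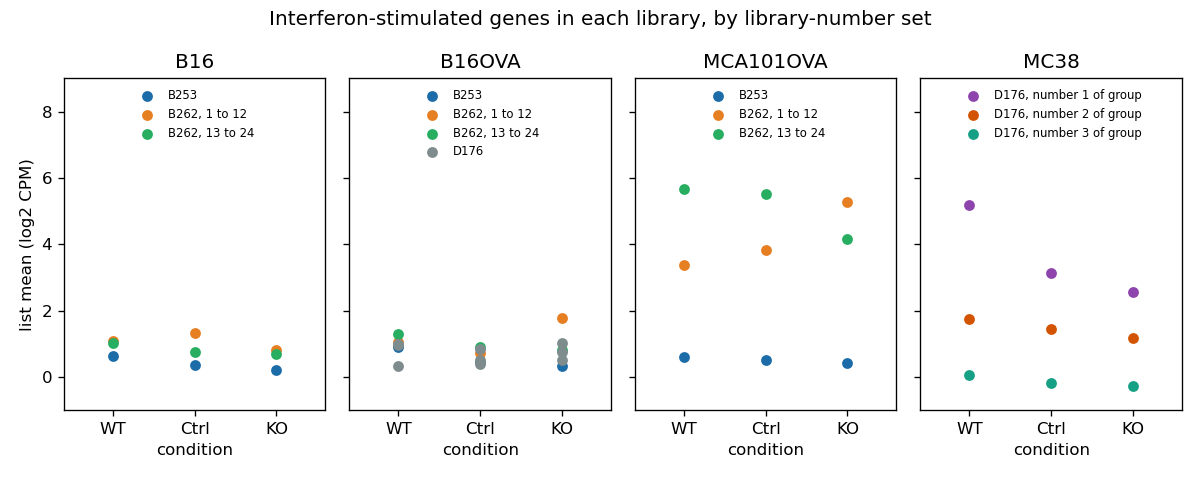
Mean log2 CPM of the 40 interferon-stimulated genes (vertical axis) in each WT, Ctrl and KO library (horizontal axis) of the 4 lines (panels); colours give the library-number set, or in MC38 the place of the library number in its group. In MCA101OVA the B253 libraries lie between 0.42 and 0.60 and the B262 libraries between 3.36 and 5.67, in WT, Ctrl and KO alike.

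Other lists were called in B16OVA and held with the preset correlation alone: proliferation genes fell (adjusted p = 6.2e-06; 0.965 with an estimated correlation), cholesterol biosynthesis genes fell (0.00816; 0.965), and p53 targets (0.0381; 0.579) and chemokine genes (0.0126; 0.579) rose. Of their members, edgeR called 1, the p53 target Gdf15 (1.94 against 0.230 CPM, log2 fold 2.86, adjusted p = 0.00139). The integrated stress response list fell in B16 (0.00161; 0.965 with an estimated correlation), and the matrix list rose in MC38 (0.0464; 0.965), where Col1a1 (log2 fold 3.15) and Col1a2 (3.50) were called up. Leaving out single libraries brought all of these lists except proliferation to an adjusted p between 0.0550 and 0.435.

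Whether the response differs between lines was tested against B16OVA. For B16, edgeR called 0 genes (249 at an unadjusted p under 0.05). For MC38, 44 genes differed (34 with the higher effect in MC38, 10 with the lower), and 67 with library sets as a replicate block. The collagen gene Col1a2 rose more in MC38 by 4.41 (SE 0.85) on the log2 scale and Zfp518b by 4.27 (SE 0.65), while the difference for P2rx7 was -3.66 (SE 0.60), with adjusted p of 0.00709, 0.00134 and 0.0016. This count was 16, 21 and 19 without MC38 Ctrl replicate 2, Ctrl replicate 3 and KO replicate 1. In MC38, all from run D176, Setdb1 fell by 0.52 on the log2 scale. In B16OVA, from runs B253, B262 and D176, it fell by 1.18. A difference between lines cannot be told apart here from one in the degree of Setdb1 loss, or from a KO effect that varies between runs. For MCA101OVA, 17 genes differed (9 higher, 8 lower; 40 with library sets as a replicate block, 39 by DESeq2), among them Dpep1 (6.28, SE 1.07, adjusted p = 0.00373) and Pcdhgb2 (3.80, SE 0.48, adjusted p = 3.34e-05). The count was 9, 11 and 11 without MCA101OVA Ctrl replicate 1, KO replicate 1 and KO replicate 3. Random regroupings of all labels called as many in 2 of 30 draws, the real one included, and in 1 of 30 with another seed; labels dealt inside each library set did so in 1 of 30, the real one alone.

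Tumour antigens are of use where healthy tissues lack them, so the raised genes were read in 12 healthy tissues. These were brain, colon, heart, kidney, liver, lymph node (LN), lung, ovary, skin, spleen, stomach and thymus. Testis and skeletal muscle were not among them, so genes low in all 12 may be present elsewhere. Of the genes raised in B16, 36 of 111 (32.4%, 95% interval 23.9 to 42.0) had a mean under 1 CPM in every tissue, as had 49 of 167 in B16OVA (29.3%, 22.6 to 36.9), 24 of 57 in MCA101OVA (42.1%, 29.1 to 55.9) and 15 of 78 in MC38 (19.23%, 11.2 to 29.7). Of all tested genes 12.8% were so. Of tested genes whose KO level lay between the lower and upper quartile of the raised genes' levels, 9.02%, 13.2%, 6.996% and 12.7% were so. Each of these shares lies outside the interval of its line except in MC38. All raised genes were counted, also those outside the quartiles, so the match in level is partial. The background was matched on KO level and not on Ctrl level, where several raised genes were near 0. Whether genes as low in Ctrl are as often under 1 CPM in every tissue was not tested. The intervals treat genes as independent, which neighbours and members of 1 family are not. Zfp981, Zfp978 and Gabrr1 stayed at or below 0.282, 0.168 and 0.226 CPM in every tissue. Others have a home tissue: Sez6l in brain (268 ± 18.5 CPM), Cyp3a41a and Cyp2b13 in liver (195 ± 83.9 and 205 ± 80.4), Cdhr2 in colon (705 ± 71.03) and Ky in heart (25.3 ± 5.18). Tumour and tissue libraries share no sequencing run, so their levels were compared as present or absent alone.

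Without any knockout, 0 genes were at 5 CPM or more in every WT library of the 4 lines and under 0.5 CPM in every healthy library. By line, B16 had Xlr3c, Brs3, Gm20618 and Gm14139, B16OVA had Xlr3c, Brs3 and Gm20618, MCA101OVA had 4930550L24Rik, Gm20744, Gm14139 and Magea8, and MC38 had Gm13230. Xlr3c averaged 43.3 ± 7.07 CPM in B16 and 36.2 ± 9.30 in B16OVA against at most 0.307 in any healthy library, and the cancer-testis gene Magea8 6.58 ± 1.18 CPM in MCA101OVA against 0. Testis was not among the healthy libraries, so expression there is not known from these data. With a minimum of 1 CPM the counts were 20, 12, 41 and 9 in B16, B16OVA, MCA101OVA and MC38.

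Against cultured melanocytes, B16OVA WT melanoma cells had higher proliferation genes and lower matrix genes: edgeR called 5127 of 15172 genes (2171 up, 2956 down). Of 32 proliferation genes 30 were higher (31 when adjusted over the list alone; camera adjusted p = 7.64e-27, 0.269 with an estimated correlation), and 26 of 29 fibroblast and matrix genes (27 over the list alone; 2.23e-11, 0.452) and 14 of 22 MHC class I genes (14; 6.47e-07, 0.269) were lower. Foxr2 was at least 3823-fold higher in B16OVA (86.4 ± 63.3 against 0 CPM), and Brs3 at least 1124-fold. Serpine2 was at least 6337-fold lower (0 against 224 ± 106 CPM), and Lox at least 20631-fold lower (0 against 795 ± 1097 CPM, led by melanocyte replicate 1). Markers of some other cell types were lower too, with 11 of 12 leukocyte genes (11 over the list alone, 0.00119, 0.566) and 5 of 6 adipocyte genes (6, 1.205e-04, 0.270). So were 3 of 6 keratinocyte genes (4, 0.0332, 0.429). The Schwann and glial, endothelial and muscle lists were not called (camera adjusted p = 0.771, 0.538 and 0.779). The 26 matrix genes all peak in melanocyte replicate 1. The pigment genes were not called as a list (1 up and 5 down of 26, adjusted p = 0.519).

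**Figure D4:**
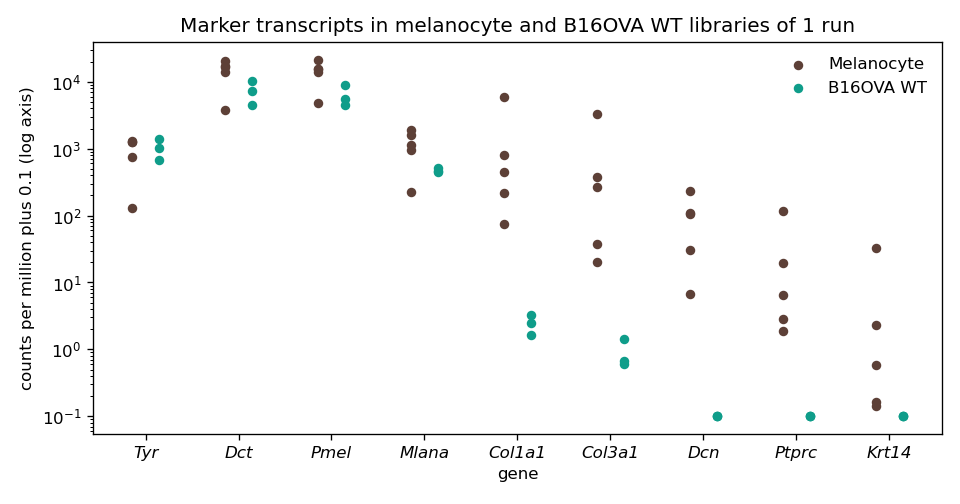
CPM plus 0.1 on a log axis (vertical) for pigment, fibroblast, leukocyte and keratinocyte marker genes (horizontal axis) in 5 melanocyte and 3 B16OVA WT libraries of 1 run; each point is a library. Col1a1 spans 75.9 to 5879 CPM over the melanocyte libraries, above every B16OVA WT library.

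Between tumour lines, B16OVA WT kept its pigment-lineage genes. It differed from MC38 WT at 4692 of 14204 genes (2688 up, 2004 down; 8008 without B16OVA WT replicate 6, 4683 of them shared) and from MCA101OVA WT at 3747 of 14266 (2053 up, 1694 down). Of 25 tested pigment-lineage genes 24 were higher than in each of these lines, also when adjusted over the list alone (camera adjusted p = 5.96e-39 against MC38 and 8.69e-53 against MCA101OVA; 0.0351 and 0.0326 with an estimated correlation). Sox10 held 708 ± 322.03 CPM in B16OVA and 0 in MC38, at least 22878-fold higher, and Gpr143 was at least 1548-fold higher than in MCA101OVA. Hoxc11 was at least 705-fold lower than in MC38, and Prl2c3 at least 10338-fold and Twist2 at least 2007-fold lower than in MCA101OVA.

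The 12 healthy tissues carried the programmes their labels name. Of 26242 tested genes 15554 were highest in 1 tissue, from 3201 in brain and 1750 in thymus to 505 in stomach, and 12 of 12 marker lists were highest in their own tissue by mean and by median. Gabra6 held 450 ± 122 CPM in brain against 0.0319 in the next tissue, Kap 5623 ± 1543 in kidney against 0.236, Krt2 11843 ± 1571 in skin against 0.738 and Rag1 2182 ± 737 in thymus against 1.37.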

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

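The tests in this part of patterns and of single libraries were chosen after seeing the data, except the regroupings of samples (that inside library sets and its other seed were added late) and the differences between lines, which were planned. Dixon's test on plain CPM, also a form chosen after seeing results, was run on 95 groups of named genes and set 12 values apart, where chance alone sets about 1 in 20 apart. These were Setdb1 at 61.2 CPM in MCA101OVA WT replicate 3, Cyp3a41a at 0.171 in B16OVA Ctrl replicate 3 and Dync1i1 at 3.60 in B16OVA Ctrl replicate 6. In melanocyte replicate 1 they were Clstn3 at 0.252, Lox at 2722, Thy1 at 1214, Tnc at 3552 and Slit3 at 661 CPM, and in melanocyte replicate 5 Mpeg1 at 1049. The others were Sftpc at 7693 CPM in lung replicate 2, Hsd3b1 at 7420 in ovary replicate 4 and Gm14139 at 21.98 in MCA101OVA WT replicate 4.

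The KO effect differed from that in B16OVA for 17 genes in MCA101OVA and 44 in MC38. On the log2 scale the differences in MCA101OVA were Dpep1 6.28, Hspa1b 4.78, Pcdhgb2 3.80, Slain1 3.15, Slc35f3 -4.99, Cnga3 -4.54, Kank4os -3.91, Grhl2 -3.25 and Nfatc4 -3.17. In MC38 they were Xdh 4.66, Col1a2 4.41, Zfp518b 4.27, Cavin2 3.92, Nid1 3.51, Zfp985 -4.74, Bglap3 -4.01, Rasip1 -4.01, Ramp3 -4.01 and P2rx7 -3.66. Without the run term the adjusted p passed the threshold upward for Hspa1b (0.105), Slain1 (0.0620), Grhl2 (0.0755), Nfatc4 (0.0755), Xdh (0.149), Zfp985 (0.0946) and Rasip1 (0.0797). Without the 7 libraries of low length slope it did so for Nfatc4 (0.0850), Xdh (0.0587), Rasip1 (0.0960) and Ramp3 (0.116).

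Of the tumour-restricted genes, libraries without replicates held Gm13230 at 28.8 CPM (MC38OVA) and 35.6 (MC38GFP), and in MCA101 Gm20744 at 1.74, Gm14139 at 1.13, Magea8 at 0.103 and 4930550L24Rik at 0.120, below its highest healthy library (0.151).

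With labels dealt again, the real labels alone gave a count as large in several comparisons. They did so for the 177 genes of B16OVA KO (1 of 30 draws, highest other 0) and the 44 genes differing in MC38 (1 of 30, highest other 1). The same held for the 8 genes up in all 4 lines (1 of 30, highest other 0). It also held for the 5127 genes between B16OVA WT and melanocytes (1 of 56, highest other 0) and the 15554 tissue genes (1 of 21, highest other 5514). Chance is not excluded by these few draws, since dealt groups mix unlike libraries, which widens their spread. The KO and Ctrl draws of these comparisons also ignored the library sets. For the 17 genes differing in MCA101OVA, all labels dealt again gave 2 of 30 as large (highest other 298), and another seed 1 of 30 (highest other 8). Labels dealt inside each library set, which part the sets as the real ones do, gave 1 of 30 (highest other 0). The outcome thus depends on the draw and on the sets, and chance cannot be excluded. With sets as a replicate block 40 genes differed. For counts of 0 every split is as large by construction, so the splits say nothing about chance: B16 against B16OVA (30 of 30; highest other 21), genes down in all 4 lines (30 of 30; 0) and Ctrl against WT in B16OVA (20 of 20; 11), B16 (10 of 10; 0), MCA101OVA (10 of 10; 64) and MC38 (10 of 10; 0). The 10 splits of 6 libraries are too few for a share under 0.05: B16 116 (1 as large; highest other 1), MCA101OVA 58 (4; 3766), MC38 78 (1; 1), B16OVA WT against MC38 WT 4692 (1; 0) and against MCA101OVA WT 3747 (1; 0). In MCA101OVA the 6 splits that leave 2 library sets whole on opposite sides called 0, 0, 12, 67, 292 and 3766; the last points to a structure of the samples, but calls do not follow from that arrangement alone, and with sets as a replicate block the real split called 84.

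Genes raised in B16OVA KO lie near one another. Of the 167, 39 have another raised gene within 200 kb, against at most 28 in 1000 random sets of tested genes (permutation p = 0.001, the smallest these can give), which argues against random placement. With 1 gene kept per symbol stem it was 31 against 26, but the step took out 6 of 167 genes and left families whose members bear other symbols, so passing it, the outcome set beforehand against shared reads, was a wrong test and reads shared by paralogs stay open. Uncalled genes near a raised gene had a mean log2 fold 0.13 above other uncalled genes (highest random 0.087), though their median was 0.03. That whole neighbourhoods may be raised is a hypothesis, tested on the data it came from.

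Fibroblast and leukocyte genes are lower in B16OVA WT than in melanocytes. All 26 fibroblast-list genes called lower (100%) peak in melanocyte replicate 1, where Col1a1 held 5879 CPM against 75.9 to 814 in the other 4, and 10 of 11 leukocyte-list genes peak in replicate 5. Cells of other types in the melanocyte cultures are therefore a candidate source. In all 5 melanocyte libraries 100% of the 26 and 100% of the 11 lie above every B16OVA WT library. These genes were chosen as called lower in B16OVA WT, so that outcome was likely beforehand. It shows that the direction holds in each library, and leaves open how far 1 library sets the size of the difference. The length slope of B16OVA WT replicate 6 alone does not account for the calls. Without that replicate 88.5% of the 26 and 81.8% of the 11 were still called lower. Melanocytes' own expression of matrix genes stays open.

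Interferon-stimulated genes vary between libraries of 1 group. No correlation with the length slope of a library was detected over all libraries (Pearson r -0.10, permutation p = 0.528), nor in run B262 (0.316, permutation p = 0.466) or D176 (-0.121, permutation p = 0.704), whose signs differ, and the lowest adjusted p of the list for Setdb1 KO was 0.965 with an estimated correlation, or 0.936 with library sets as a replicate block, where the preset correlation called the list down in MC38 (0.00307), so a part of Setdb1 loss stays open. The library-number set took up 91.4% of the spread within groups in MCA101OVA (exact p = 0.0556, adjusted 0.0741) and 92.2% in MC38 (exact p = 0.0278, adjusted 0.0556), 87.5% in B16 (exact p = 0.0278, adjusted 0.0556) and 40.7% in B16OVA (permutation p = 0.0896). By adjusted p all 4 lines stayed over 0.05, and 0.0278 is the smallest p that 36 arrangements allow, so whether the set is the source stays open.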

How the results depend on the processing

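The fits without the 7 libraries of low length slope, with the slope as a covariate, with Ctrl and WT together and with the block by line were chosen after seeing the data; the others were planned. Of 3220 values under alternatives, 2926 kept their direction and side of the threshold or stayed within 1.5 times, and 0 reversed. Of 2798 for named genes, lists and levels, 199 were weaker and 21 stronger. A further 10, all Setdb1 group means, moved by their SD or more with TMM factors. Of 422 counts, 64 moved by over 1.5 times. For those below the cause was not tested, except that with fewer libraries in a fit fewer degrees of freedom remain.

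KO against Ctrl: B16 (116) gave 22 with the 2 groups alone and 74 to 108 leaving out single libraries. B16OVA (177) gave 296 with no filter, 275 with the replicate block by line and, rounded, 1.1e2 with the 2 groups alone. MCA101OVA (58) gave 144 with no filter, 1 with the 2 groups alone, 117 with Ctrl and WT together and 34 to 81 leaving out single libraries. MC38 (78) gave 145 with no filter, 134 with the replicate block by line, 141 with the slope, 2 with the 2 groups alone, 131 with WT in place of Ctrl, 191 with Ctrl and WT together and 27 to 99 leaving out single libraries. Genes up in all 4 lines (8) were 14 with no filter, 16 with Ctrl and WT together and 5 to 9 leaving out single libraries. With WT in place of Ctrl the share of raised genes in B16OVA went from 94.4% to 83.2%.

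Ctrl against WT (0) gave 1, 37, 5 and 40 with no filter in B16, B16OVA, MCA101OVA and MC38. It gave 11 in B16OVA without the 7 libraries and 0 to 1 leaving out single libraries, 1 in MCA101OVA with DESeq2 and 1 in MC38 with the slope. Differences from B16OVA: B16 (0) gave 22 with no filter and 0 to 1 leaving out single libraries. MCA101OVA (17) gave 55 with no filter, 39 with DESeq2, 10 without the run term, 40 with the block by line, 29 with the slope and 9 to 18 leaving out single libraries. MC38 (44) gave 96 with no filter, 67 with the block by line, 80 with the slope and 16 to 49 leaving out single libraries.

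The replicate block by library-number set gave 133, 218, 77 and 113 KO genes in B16, B16OVA, MCA101OVA and MC38, and the block by line 152, 275, 84 and 134. In MC38 pairing by the order of library numbers is a hint from the data, not the design. Called lists numbered 16, with 17 under the set block, 19 under the block by line, 13 without the 7 libraries and 12 with the slope.

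B16OVA WT against MC38 WT (4692) gave 8008 without the library of low length slope and 3288 to 8008 leaving out single libraries. With no filter the median of all genes against melanocytes moved to -0.18. Tissue genes (15554) were 24437 with no filter and 9010 at a log2 fold of at least 4. Tumour-restricted genes in all 4 lines (0) were 1 at a CPM of at least 1; in B16, B16OVA, MCA101OVA and MC38 (4, 3, 4 and 1) they were 20, 12, 41 and 9 at that minimum and 0, 0, 1 and 0 under 0.1 CPM in healthy libraries. MCA101OVA had 0 at a CPM of at least 10, and MCA101OVA and MC38 had 11 and 4 under 1 CPM in healthy libraries.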

Other observations

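In B16OVA, Atf7ip, whose product partners with Setdb1 in heterochromatin, rose on Setdb1 loss from 83.9 to 227 CPM (log2 fold 1.44, edgeR adjusted p = 6.35e-04). In B16 it stood at 183 against 80.6 CPM (log2 fold 1.21, adjusted p = 0.237, and 0.0234 over its list alone). The myelin gene Mbp rose in B16OVA from 36.2 to 114 CPM (log2 fold 1.49, adjusted p = 0.0358).

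Setdb1 itself varied between healthy tissues, from 23.6 ± 4.54 CPM in heart to 112 ± 17.2 in thymus, with 44.3 ± 11.8 in melanocytes. With TMM factors the means were 37.9 in heart and 89.7 in thymus, and liver went from 34.0 to 72.6, so the order of tissues depends on the scale. The single libraries held 91.7 CPM (MC38OVA), 115 (MC38GFP) and 96.0 (MCA101).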
